A study of Mus musculus with 6 samples.

How the data were processed

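Polyadenylated RNA from mouse liver was sequenced in 6 libraries, 3 without and 3 with DEHP, as paired ends from a strand-marking kit, per the labels' protocols. The deposited counts are whole-number counts of reads per gene, in 1 table with a column per library. The submitters' processing notes name the genome build GRCm38.p6; the aligner, the counting program and whether counting used strand are not given in the sources used here. The exposed columns carry the word High, and the dose is not given in the sources used here. The design text describes another assay, bisulfite sequencing of a human cell line, so groups were taken from the sample titles alone.

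The 41096 annotated rows carry gene identifiers of the Ensembl C57BL/6NJ strain annotation. Of 29750 symbols shared with GENCODE M21 on GRCm38, 29701 lay on the same chromosome and 0 had the same start and end, so coordinates are given only as the table has them. The table of 42380 rows holds 1284 loci without a gene name, which took 2.73% to 4.28% of counts; these stayed out of library sizes and tests. Another 10687 rows carry an identifier in place of a symbol and took 3.48% to 4.28% of counts; they were tested but match no list. No row lies on a mitochondrial chromosome or on chromosome Y. Of 6 rows that carry mitochondrial gene names and lie on nuclear chromosomes, 2 had any count and 1 was tested. The list of mitochondrially encoded genes had 0 tested members and was not analysed here. Cyp4a10, Map1lc3b and Saa1 have no row under their symbols. The 2 rows described as Cyp4a10 had log2 fold changes of 1.54 ± 0.55 and 0.34 ± 0.90 (SE, adjusted p = 0.345 and 0.914).

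Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10, TMM scaling, and the robust quasi-likelihood test of exposed against control livers with no covariate, two-sided, with Benjamini-Hochberg adjustment over 12468 genes and a threshold of 0.05. Fold changes are log2 of exposed over control, with standard errors derived from the F statistic; CPM are relative to the TMM-scaled total of the annotated entries that passed the filter, given as mean ± SD over 3 libraries. The common biological coefficient of variation was 27.9%. Gene lists were fixed before the data were examined, 62 in all; 55 had at least 5 tested members, 7 did not, and the 55 entered camera from limma 3.58.1, on log2 CPM with a prior count of 2, with a preset correlation of 0.01. Camera with an estimated correlation and the fry test were alternatives.

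Named genes followed a rule fixed in advance: 18 genes named in every case, of which 15 had a row, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 CPM and groups that do not overlap (predicted genes and pseudogenes replaced by the next gene), up to 4 members past the threshold from each list, and otherwise the 2 most abundant members of a main list. Genes named outside it are given as picked after their values were seen. Not every gene that the rule names is reported here. Alternatives fixed in advance were RLE scaling, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, a fit that is not robust, a replicate block, a minimum log2 fold change of 1, mitochondrially named genes left out, and each library left out. Adding unnamed loci, leaving out control replicates 1 and 2, and matching list members by description were chosen after the data were seen.

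The test was checked on simulated counts with the means, library sizes and dispersions of these libraries. Of 100 genes changed by 1 on the log2 scale, 18% were recovered, and of 100 changed by 2, 83%; 11 of 112 calls among 12195 genes were false, more than the threshold of 0.05 aims at. In a simulation over 12161 genes in which PPARalpha targets alone were raised by 0.5, that list passed and 0 others did. Genes were drawn independently of each other there, while the correlation estimated among PPARalpha targets in these libraries was 0.44. That simulation therefore cannot show how often lists whose members vary together pass wrongly. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 31.1 for any pair. Each was counted as 1 sample, and the chi-square cannot tell separate animals from repeated preparations of 1 liver.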

Results

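Messenger RNA was sequenced from mouse liver, with or without exposure to DEHP, di(2-ethylhexyl) phthalate, a plasticizer. There were 6 libraries, 3 from control livers and 3 from exposed livers, each deposited as whole-number counts per gene. Total counts were 14229803, 12562759 and 12001969 in control replicates 1 to 3, and 10410098, 12405044 and 11955138 in the exposed replicates. Group means were 12931510 ± 1158790 and 11590093 ± 1046373 (SD, n = 3, two-sided exact permutation p = 0.2, where the smallest possible p is 0.1). The labels name no dose, duration, age or sex. They do not say that the libraries came from separate animals, so the p-values measure the spread between these samples.

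The comparison asked which liver transcripts differ with DEHP. Cyp2b10, a cytochrome P450 induced through the nuclear receptor CAR, rose most, by 5.39 ± 0.48 on the log2 scale (SE, adjusted p = 2.82e-04), from 0.460 ± 0.217 to 20.1 ± 8.82 CPM (SD, n = 3; library-scaled counts). Cd36, a fatty acid uptake receptor, rose by 2.26 ± 0.22 (adjusted p = 3.51e-04), from 23.4 ± 5.13 to 112 ± 16.7 CPM. Lpl, which encodes lipoprotein lipase, rose by 1.30 ± 0.21 (adjusted p = 0.0339), from 22.4 ± 4.83 to 55.4 ± 6.41 CPM. Serpina12, which encodes the serpin vaspin, fell by 2.30 ± 0.33 (adjusted p = 0.0193), from 28.5 ± 7.63 to 5.76 ± 2.82 CPM. Sod3, the extracellular superoxide dismutase, fell by 1.17 ± 0.20 (adjusted p = 0.0422), from 41.7 ± 3.42 to 18.5 ± 1.55 CPM. All 3 exposed libraries lay beyond all 3 controls for each of these genes.

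In all, 9 of 12468 genes tested passed an adjusted p of 0.05, 7 higher and 2 lower in exposed livers. The other 4 that rose were Krt23, a type I keratin (log2 fold change 3.50 ± 0.41, adjusted p = 0.00250), Gpcpd1, a glycerophosphocholine phosphodiesterase (1.94 ± 0.27, adjusted p = 0.0188), and 2 more. These were Sugct, a mitochondrial glutarate-CoA transferase (1.53 ± 0.19, adjusted p = 0.00410), and Ppia, which encodes cyclophilin A (1.88 ± 0.27, adjusted p = 0.0188). The Ppia value is uncertain because 48 entries of the table are described as Ppia, pseudogenes among them. Summed over these, CPM was 92.2 ± 14.0 in controls and 164 ± 24.7 in exposed livers (two-sided exact permutation p = 0.1, the smallest possible). At an unadjusted p of 0.05 there were 1631 genes, against 623 expected by chance. The groups did not overlap for 2211 genes, 17.7% of those tested, where chance gives 10%. Genes that vary together can carry both counts far from these chance levels, and interferon-stimulated genes had an estimated correlation of 0.94. The counts therefore do not give a number of genes changed by DEHP. With 1 library left out, the first count ran from 949 (control replicate 1) to 2058 (control replicate 3).

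**Figure D1:**
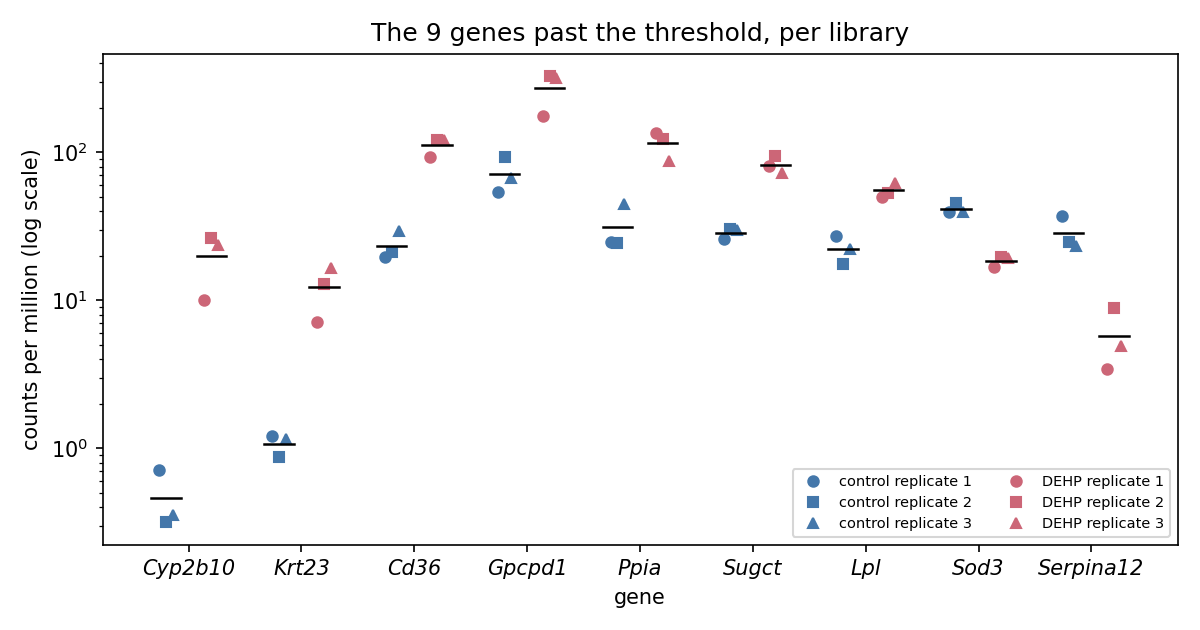
CPM on a log scale for each of the 9 genes past the threshold, with a point per library (blue for control, red for DEHP) and black lines at group means of 3 libraries. The groups do not overlap for any of the 9 genes, and Cyp2b10 separates most, at 0.460 CPM in controls and 20.1 CPM in exposed livers.

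In the coordinates of the deposited table, which carries the annotation of the C57BL/6NJ strain, Cyp2b10 spans chromosome 7 from 25249046 to 25286370, Cd36 chromosome 5 from 16469833 to 16584935, and Lpl chromosome 8 from 71612060 to 71641079. Krt23 spans chromosome 11 from 105280842 to 105295969. Serpina12 spans chromosome 12 from 109096519 to 109112179, and Sod3 chromosome 5 from 53472655 to 53480341. All 6 are annotated as protein-coding. Cyp2b10, Cd36, Krt23 and Sugct passed whichever library was left out, while among these 6 fits Sod3 passed only without control replicate 3. Lpl, Ppia, Gpcpd1 and Serpina12 each missed the threshold without control replicate 1 and without at least 1 other library. The number of calls was 5 without control replicate 1, 6 without control replicate 2, 400 without control replicate 3, and 19, 6 and 5 without DEHP replicates 1, 2 and 3. It was 272 with DESeq2 and 496 with edgeR and no low-count filter. Limma-voom called 7 genes and missed Cyp2b10 (adjusted p = 0.121), Krt23 and Sod3 (0.0582 each). A fit that was not robust called 8 and missed Lpl and Sod3 (0.0620 each). With control replicates 1 and 2 both left out, a choice made after the data were seen, none passed (edgeR, 642 at an unadjusted p of 0.05).

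Among peroxisome proliferator-activated receptor alpha targets, many of them genes of fatty acid oxidation, 0 of 39 tested passed over all genes (edgeR, 13 higher and 1 lower at an unadjusted p of 0.05). Adjusted over the list alone, 6 passed, all higher. Over all genes, DESeq2 called 5 and limma-voom 0, edgeR with no filter called 8 higher and 1 lower, and 9 passed without control replicate 3, all higher. The list as a whole was higher in exposed livers (median log2 fold change 0.37, 33 of 39 positive, camera adjusted p = 3.13e-09), with adjusted p = 0.445 with an estimated correlation. Its median was 0.22 without control replicate 1 and 0.60 without control replicate 3. Cyp4a14, the fatty acid omega-hydroxylase, had a log2 fold change of 1.16 ± 0.40 (adjusted p = 0.303). It had 2232 CPM in control replicate 3, against 858 and 714 in the other controls and 2630 to 3256 in exposed livers. Values for Acot1 (0.88 ± 0.64, adjusted p = 0.618) and Cpt1a (0.49 ± 0.22, adjusted p = 0.366) did not pass. Without control replicate 3, Cyp4a14 (adjusted p = 1.31e-04) and Acot1 (0.0274) did. Fgf21, a hormone of fasting, had -2.21 ± 0.76 (adjusted p = 0.281, and 0.00804 with no filter), and -1.18 (0.753) without control replicate 1, which held 9.43 CPM against 2.21 and 2.39 in the other controls. Ehhadh, the peroxisomal bifunctional enzyme (1.22 ± 0.25), and Vnn1, vanin (0.92 ± 0.21), had the smallest list-alone p, 0.0104 each, and were picked after their values were seen. The median of the list in control replicate 3 lay at -0.08 from the exposed mean on the log2 scale, against -0.82 and -0.36 in control replicates 1 and 2. With those 2 left out the list did not pass (median 0.11, adjusted p = 0.121).

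Of 30 targets of the receptors CAR and PXR, Cyp2b10 passed over all genes, and 10 higher and 2 lower passed adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 3.85e-06), with adjusted p = 0.409 with an estimated correlation. Over all genes, 6 higher and 1 lower passed without control replicate 3, 1 higher and 1 lower without DEHP replicate 1, 7 higher and 1 lower with DESeq2, 9 higher and 1 lower of 31 with no filter, and 0 with limma-voom. The list median lay at -0.54, -0.36 and -0.31 from the exposed mean in control replicates 1 to 3. Por, the reductase that supplies electrons to cytochromes P450, had a log2 fold change of 1.02 ± 0.21 and a list-alone p of 0.00232. Gstm3, a glutathione transferase, lay at -1.24 ± 0.26 with the same p, and both were picked after their values were seen. Over 48 cytochrome P450 genes the median was 0.45 (camera adjusted p = 1.50e-07), with adjusted p = 0.409 with an estimated correlation. Of these, 1 passed over all genes, 2 of 49 without DEHP replicate 1 and 12 of 49 without control replicate 3, all higher. DESeq2 called 7, all higher, limma-voom 0, and edgeR with no filter 14 higher and 1 lower of 61. Glutathione S-transferase genes (median 0.12, adjusted p = 0.494), carboxylesterase genes (-0.07, 0.939) and aryl hydrocarbon receptor targets (median 0.20, 0.736) did not pass as lists. Nor did NRF2 and oxidative stress genes (median 0.05 and a mean of the other sign, -2.24e-04, adjusted p = 0.461). The aryl hydrocarbon receptor median was -0.05 without control replicate 1. The NRF2 median was -0.04 without DEHP replicate 1 and 0.28 without control replicates 1 and 2. With all libraries and an estimated correlation its camera adjusted p was 0.724. The glutathione S-transferase median ran from 0.02 without control replicate 1 to 0.23 without control replicate 3, and the carboxylesterase median from -0.18 without DEHP replicate 2 to 0.01 without DEHP replicate 3. These last 2 families passed the mixed fry test, which asks whether members change in either direction (adjusted p = 0.0139 and 0.0211). Cyp2e1, the ethanol-inducible form, stood at 9517 ± 3176 and 19762 ± 1141 CPM (1.05 ± 0.25, adjusted p = 0.151). Aldh1a1, a retinal dehydrogenase, lay at 0.75 ± 0.19 (adjusted p = 0.169), and Cyp3a11, at 3.50 and 4.03 CPM, at 0.22 ± 0.53 (adjusted p = 0.904). The Cyp3a11 row held only 22 to 83 counts a library, so its value does not show that the gene did not respond. Whether its reads lay in rows of related genes was not tested. A row described as Cyp2b9, a close relative of Cyp2b10, fell below the filter, with 0, 1 and 3 counts in controls and 84, 9 and 103 in exposed livers. These genes share sequence, so their counts are uncertain.

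Bile acid and sterol efflux genes had a median log2 fold change of 0.60, with 18 of 23 positive. Over all genes 0 passed (edgeR, 12 higher and 1 lower at an unadjusted p of 0.05), and 11 higher and 1 lower passed adjusted over the list alone. The list passed (camera adjusted p = 1.50e-07), with adjusted p = 0.409 with an estimated correlation. Its median was 0.37 without control replicate 1, and 5 of its members passed over all genes without control replicate 3 and 1 without DEHP replicate 1, all higher. DESeq2 called 6 and limma-voom 0. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 32.1 ± 2.22 CPM in controls and 103 ± 44.9 in exposed livers (log2 fold change 1.69 ± 0.30, adjusted p = 0.120), and passed without control replicate 3 (0.0162). Cyp27a1, a sterol 27-hydroxylase, had 0.61 ± 0.22 (adjusted p = 0.281), and Slc27a5, the bile acid CoA ligase, 0.64 ± 0.20 (adjusted p = 0.237).

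For lipid storage and synthesis, 23 steatosis and lipid droplet genes included Cd36 and Lpl, the 2 that passed over all genes (list median 0.21, camera adjusted p = 0.00508), with adjusted p = 0.467 with an estimated correlation and 0.0701 without DEHP replicate 3 (median 0.12). Adjusted over the list alone, 4 higher and 1 lower passed. Over all genes, 1 passed without control replicate 1, control replicate 2, DEHP replicate 2 or DEHP replicate 3, 3 passed without control replicate 3, and DESeq2 called 4 higher and 1 lower and limma-voom 2. De novo lipogenesis did not pass as a list (median 0.08, adjusted p = 0.292). Its median was -0.04 without control replicate 1 and 0.21 without control replicate 3, where 2 members passed as lower. Fasn, fatty acid synthase, had -0.39 ± 0.24 (adjusted p = 0.507), Scd1, a stearoyl-CoA desaturase, 0.45 ± 0.37 (adjusted p = 0.658), and Dgat2, which makes triglyceride, 0.13 ± 0.20 (adjusted p = 0.823). Cholesterol synthesis and uptake did not pass with all libraries (median 0.14, camera adjusted p = 0.186, and 0.675 with an estimated correlation). With the preset correlation it passed without control replicate 1 (median 0.28, adjusted p = 0.00984) or DEHP replicate 1 (0.21, 0.0286). The median was 0.03 without control replicate 2 or DEHP replicate 3. Lipoprotein assembly did not pass (median 0.06, mean -0.06, adjusted p = 0.633).

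Autophagy and mitochondria are named in the title of the series. Of 56 autophagy machinery genes, 0 passed over all genes or adjusted over the list alone (edgeR, 9 higher and 2 lower at an unadjusted p of 0.05; DESeq2 and limma-voom 0). The list missed the threshold (median 0.06, adjusted p = 0.0564, and 0.409 with an estimated correlation). It passed with RLE scaling (0.0469), DESeq2 (0.0468), a mean of at least 1 CPM (0.0495) and no filter (0.0134). It also passed without control replicate 3 (0.0210), DEHP replicate 2 (0.0444) or DEHP replicate 3 (0.0298), and not without control replicate 1 (0.113), control replicate 2 (0.108) or DEHP replicate 1 (0.140). Its median was 0.02 without DEHP replicate 1 and 0.15 without control replicate 3. Sqstm1, the cargo receptor p62, was 614 ± 44.7 CPM in controls and 615 ± 64.1 in exposed livers (log2 fold change 0.00 ± 0.19, adjusted p = 0.996). Becn1 (0.18 ± 0.20, adjusted p = 0.740) and Gabarapl1 (0.54 ± 0.23, adjusted p = 0.344) did not pass, and the lysosome list had a median of -0.04 (adjusted p = 0.773) and passed the mixed fry test (adjusted p = 0.00691). The lysosome median was 0.02 without control replicate 2, and 3 of 54 members passed as lower without control replicate 3, as 2 did with DESeq2. The mitophagy and mitochondrial dynamics list was higher in exposed livers (median 0.16, 23 of 30 positive, camera adjusted p = 5.82e-04), with adjusted p = 0.409 with an estimated correlation. Its median was 0.30 without control replicate 3 and 0.26 without DEHP replicate 1. Bnip3, a mitophagy receptor and the list's single member past the threshold adjusted over the list alone (0.00405), had 1.10 ± 0.21 and was picked after its values were seen. Pink1, a kinase that marks damaged mitochondria, had 0.44 ± 0.18 (adjusted p = 0.334). Nuclear genes of respiratory complexes II to V were higher (median 0.23, 32 of 40 positive, camera adjusted p = 5.56e-06), with adjusted p = 0.452 with an estimated correlation and a median of 0.36 without control replicate 3 or DEHP replicate 1. Without control replicate 2 the median was 0.17 (adjusted p = 0.0222). That library lay at -0.43 from the exposed mean, against -0.15 and -0.13 in control replicates 1 and 3 and -0.14 in DEHP replicate 1. The ATP synthase subunit genes Atp5a1 and Atp5b had 0.38 ± 0.20 and 0.45 ± 0.21. Complex I was higher too (median 0.11, camera adjusted p = 0.00640), with adjusted p = 0.560 with an estimated correlation and 0.453 without control replicate 2. Its median ran from 0.04 without control replicate 2 to 0.21 without control replicate 3. Mitochondrial biogenesis did not pass (median 0.08, adjusted p = 0.124, and 0.0373 in the mixed fry test), with Tfam, which maintains mitochondrial DNA, at 0.11 ± 0.20 and Ppargc1a, the coactivator PGC-1alpha, at 0.38 ± 0.40.

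Interferon-stimulated genes, the antiviral genes switched on by interferon, had the lowest median of the lists tested, -2.81, with all 31 negative (camera adjusted p = 1.70e-19), and adjusted p = 0.409 with an estimated correlation. Over all genes 0 passed (edgeR, 27 lower at an unadjusted p of 0.05), while DESeq2 called 15, limma-voom 0 and edgeR with no filter 7 of 33, all lower. Without control replicate 3 all 33 tested passed as lower. Stat2 and Mx2 passed adjusted over the list alone (0.0113 each) and were picked after their values were seen. Irf7, an interferon regulatory factor, reached 1073 and 820 CPM in control replicates 1 and 2, and 32.4 CPM in control replicate 3, against 52.3 ± 11.0 in exposed livers (log2 fold change -3.62 ± 1.34, adjusted p = 0.382). Bst2, tetherin, was 1014, 686 and 161 CPM in controls and 164 ± 29.9 in exposed livers (-1.92 ± 0.68, adjusted p = 0.356). The acute phase list was lower too (median -0.54, camera adjusted p = 3.06e-04), with adjusted p = 0.479 with an estimated correlation. Of its members 0 passed over all genes (edgeR, 1 higher and 10 lower at an unadjusted p of 0.05), while DESeq2 called 4, limma-voom 0, and edgeR without control replicate 3 13 of 30, all lower. Hp, haptoglobin, had 23965, 15810 and 8305 CPM in controls and 8410 ± 2174 in exposed livers (-0.93 ± 0.35, adjusted p = 0.320). Hpx, hemopexin, had -1.16 ± 0.30 (adjusted p = 0.178). Macrophage and Kupffer cell markers were lower as a list (median -0.67 over 16 genes, camera adjusted p = 0.0102), with adjusted p = 0.653 with an estimated correlation and 0.233, 0.232 and 0.274 without control replicate 1, control replicate 2 or DEHP replicate 1. The macrophage median was -0.45 without control replicate 2, and 8 of its 16 genes passed as lower without control replicate 3. Immediate-early and heat shock genes, which respond to tissue handling, were also lower as a list (median -0.43, 18 of 23 negative, camera adjusted p = 0.00640), with adjusted p = 0.409 with an estimated correlation and 0.0570 without control replicate 1. The exposed livers were also set against control replicate 3 alone, a choice made after the data were seen. That library alone gives no spread among controls. Interferon-stimulated genes then had a median of 0.24, acute phase genes 0.03 and macrophage markers 0.47. The negative medians of all 3 lists rested on control replicates 1 and 2.

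**Figure D2:**
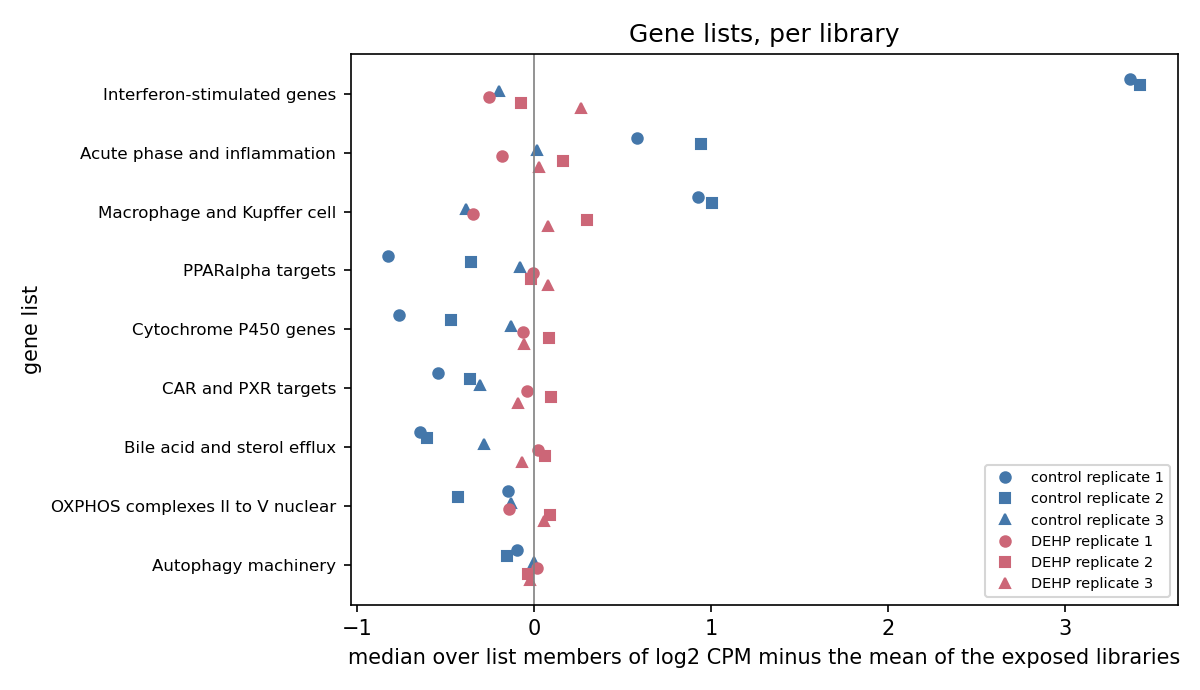
For 9 gene lists, the median over members of log2 CPM minus the mean of the exposed libraries, on the horizontal axis, with a point per library, blue for control and red for DEHP. Control replicates 1 and 2 lie at 3.37 and 3.42 for interferon-stimulated genes, and control replicate 3 at -0.20, among the exposed libraries.

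Over all lists, 25 of the 55 tested passed with a preset correlation, 17 higher and 8 lower in exposed livers. Lists share members, so the 25 are not separate results. For example, Cd36 is in the steatosis and female-biased lists, and Cyp4a14 in the PPARalpha, cytochrome P450 and female-biased lists. Aldh1a1 is in the CAR and PXR and the pericentral lists. With an estimated correlation 0 passed (lowest adjusted p = 0.409), and 0 passed the directional fry test (lowest adjusted p = 0.205). Of the 25, 8 passed the mixed fry test, and 15 passed whichever library was left out. With control replicates 1 and 2 left out, 1 control library remained. A list passing there cannot be told from a difference between single livers, so those calls are not counted. Splits that mixed exposed and control libraries still gave 5 to 23 lists. The medians then were 0.36 for CAR and PXR targets, 0.29 for bile acid genes, 0.20 for cytochrome P450 genes and 0.17 for mitophagy genes. The steatosis list (median 0.03), complex I (0.05) and complexes II to V (0.16) did not pass there. Another 4 lists did not pass with all libraries. Against the lone control their medians were 0.28 (NRF2 targets), -0.35 (fibrosis and stellate activation), 0.16 (proteasome subunit genes) and 0.08 (mitochondrial ribosomal proteins). Fibrosis genes passed without control replicate 2 (0.00653) or DEHP replicate 3 (0.00172) and with no filter (0.0465). Mitochondrial ribosomal proteins also passed without control replicate 1 (0.0238) and with no filter (0.0261). Proteasome genes passed as lower without control replicate 3 (median -0.20, adjusted p = 0.00502).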

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

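The tests of control replicate 3, of immune cells, of metabolic lists and of Ppia copies were chosen after the result was seen; the splits of the samples were planned.

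Loci without a gene name, which the comparisons do not use, took 3.74 ± 0.468% of counts in exposed livers and 2.82 ± 0.0905% in controls (SD, n = 3, two-sided exact permutation p = 0.1, the smallest possible), a signal above the controls in data outside the main measurement. Of these, 1 locus on an unplaced contig took 2.45 ± 0.520% and 1.60 ± 0.191%. Its log2 fold change was 0.68 ± 0.23 (SE, edgeR adjusted p = 0.276), and 0 of the 516 such loci tested passed, with 70 at an unadjusted p of 0.05. Without that locus the groups overlapped. The remaining share was 1.35, 1.18 and 1.14% in control replicates 1 to 3, and 1.27, 1.25 and 1.37% in the exposed replicates.

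Control replicate 3 lay with the exposed libraries for interferon-stimulated genes, at -0.198 on the log2 scale from the exposed mean, while the other controls lay at 3.37 and 3.42. Pearson correlations of log2 CPM were taken over all genes tested, interferon-stimulated genes included. Control replicate 3 had 0.963, 0.947 and 0.966 with DEHP replicates 1 to 3, and 0.942 and 0.948 with control replicates 1 and 2. DEHP replicates 1 and 2 had 0.946 with each other, and control replicate 2 had 0.949 with DEHP replicate 3. These correlations did not sort the libraries by group, and none was computed without interferon-stimulated genes. Whether control replicate 3 was mislabelled stays open. Cyp2b10, named in advance and picked for this test afterwards, lay there at -6.79 standard deviations of the 3 exposed libraries from their mean (0.354 CPM). Positions were set with 0 as the control and 1 as the exposed mean of the other libraries. Cyp2b10, Cd36 and Cyp7a1 lay at -0.07, 0.21 and 0.04, but Cyp4a14 and Acot1 at 0.82 and 1.05. Over the 100 genes with the smallest p that were lower in exposed livers among the other libraries, the median was 1.02. Over 100 higher genes it was 0.588. Left out in the same way, DEHP replicates 1 to 3 lay at 0.418, 0.923 and 0.633 over lower genes, and 0.495, 1.085 and 0.815 over higher genes. Control replicates 1 and 2 lay at 0.05 and 0.32 over lower genes, and -0.16 and 0.30 over higher genes. For more macrophages, T, NK or B cells in the control livers, the lowest median of their marker lists was -0.673. That lay above the upper quartile of -2.46 for interferon-stimulated genes, so none of these lists fell as far. Macrophage markers still lay at 0.92 and 1.005 from the exposed mean in control replicates 1 and 2, and at -0.38 in control replicate 3. T and NK markers lay at 0.68, 0.28 and -0.55 there, and B cell markers at -0.52, -0.91 and -0.68. A gain of immune cells smaller than the interferon difference stays open, as do neutrophils, with 3 tested markers. Whether DEHP lowers interferon-stimulated genes, or control replicates 1 and 2 were in an interferon state of another origin, cannot be told apart. A single unexposed library holds the low level.

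Several metabolic gene lists were higher in exposed livers, PPARalpha targets among them, each with a call that is lost with an estimated correlation (adjusted p = 0.445 for PPARalpha targets). Control replicate 3 lay close to the exposed mean for PPARalpha targets, at -0.0820, and further below it for acyl-CoA thioesterases (-0.54), CAR and PXR targets (-0.31) and bile acid genes (-0.28). The interferon and acute phase state of control replicates 1 and 2 may hold part of the list differences. Of the genes named in every case that passed without control replicate 3, Cyp4a14 and Acot1 lay near the exposed level in that library (positions 0.82 and 1.05), and Cyp2b10, Cd36 and Cyp7a1 near the control level (-0.07, 0.21 and 0.04). An effect of DEHP on these lists and the state of 2 control livers cannot be told apart, since 1 library excludes nothing.

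Ppia was higher in exposed livers, and reads shared with its pseudogenes could produce such a difference. The sum over 48 rows described as Ppia had a log2 ratio of 0.831 ± 0.180 (SE). Sharing alone would give 0 if every shared read were counted once among these rows. The counting program is not known, so the sum cannot decide whether sharing is the whole cause. The other rows together had a log2 ratio of -0.32, so part of the 1.88 measured at the Ppia row may be reads moved between copies. An effect of DEHP on Ppia stays open, as untested.

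The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 9 genes and the highest of the other splits 0, so 1 split gave as many. For lists the real split gave 25 and the highest other 23, again 1 split. Splits that grouped control replicates 1 and 2 with DEHP replicate 1, 2 or 3 gave 21, 22 and 23 lists, and the remaining ones 5 to 15. The number of list calls thus went with control replicates 1 and 2 and does not single out the exposure.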

How the results depend on the processing

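The tests without control replicates 1 and 2, with unnamed loci and with members matched by description were chosen after the data were seen. The 9 called genes kept their direction in all 16 alternatives. All 9 passed with mitochondrially named genes left out, RLE scaling, a mean of at least 1 CPM, a minimum log2 fold change of 1, no filter and DESeq2. No filter gave 496 genes (220 higher, 276 lower), 478 of them also tested in the main analysis, and DESeq2 272 (117 higher, 155 lower), of which 271 had an unadjusted p under 0.05 in the main test; the cause was not tested. Leaving out 1 library gave 5 to 400 genes in total, 4 to 122 higher and 0 to 278 lower: 5 without control replicate 1, 6 without control replicate 2, 400 without control replicate 3, 19 without DEHP replicate 1, 6 without DEHP replicate 2 and 5 without DEHP replicate 3 (losses go with fewer samples; the cause of the gains without control replicate 3 and DEHP replicate 1 was not tested). With control replicates 1 and 2 left out, 0 genes passed (0 higher, 0 lower), where the lone control is assumed to vary like the exposed libraries. Lower genes numbered 1 with limma-voom, which called 7 in total and missed Cyp2b10, Krt23 and Sod3, and 1 with unnamed loci included, where Sod3 was missed. A replicate block gave 6 genes, 1 of them lower, with 5 of the 9 kept and Ppia (adjusted p = 0.164), Lpl, Serpina12 and Sod3 (0.144 each) lost; replicate numbers are only a shared number, since same-numbered libraries had deviation correlations of -0.02, 0.06 and -0.03 and not every library correlated best with its own number. The list calls fell from 25 to 0 (0 higher, 0 lower) with an estimated correlation and to 0 (0 higher, 0 lower) with directional fry; 18 of all lists passed mixed fry, and 15 of the 25 kept their call whichever library was left out. Without control replicates 1 and 2, 13 of the 55 lists had a median of the other sign, and 17 the other camera direction. Of these 17, 4 passed with all libraries or without those 2: acute phase (median 0.03, adjusted p = 0.458), interferon-stimulated (0.24, 0.220), macrophage (0.47, 2.41e-04) and proteasome subunit genes (0.16, 0.0349). A fit that is not robust, a choice that does not enter the list test, gave 8 genes, 7 of them among the 9, and missed Lpl and Sod3. At these depths and 3 libraries a group, 18% of simulated changes of 1 on the log2 scale were recovered. Of the 59 other named genes, 24 changed sign in at least 1 alternative, 14 passed in at least 1, and 41 moved by over 1.5 times without 1 library, as 0 of the 9 did. List medians moved as far for 16 of the 25 lists that passed, none with a change of sign, and for 29 of the 30 others, 14 of them with one.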

Other observations

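The lists in this part were fixed with the others. Cell type markers other than macrophages also differed as lists. Stellate cell markers had a median log2 fold change of -0.76 (13 of 15 negative, camera adjusted p = 1.46e-04), with adjusted p = 0.409 with an estimated correlation; Ecm1 (-1.05 ± 0.22, SE) and Colec11 (-0.95 ± 0.21), picked after their values were seen, had list-alone p of 0.00286 each. The stellate median was -0.45 without control replicate 2 and -0.47 without control replicate 3. Sinusoidal endothelial markers had a median of -0.35 (17 of 18 negative, camera adjusted p = 2.40e-04), with adjusted p = 0.487 with an estimated correlation, and collagen genes -0.48 (adjusted p = 0.00342), with adjusted p = 0.510 with an estimated correlation and 0.13 without control replicate 3 (median -0.19). The endothelial median was -0.21 without DEHP replicate 2 and -0.59 without DEHP replicate 3. B and plasma cell markers had a median of 0.84 (9 of 11 positive, camera adjusted p = 0.00342), with adjusted p = 0.409 with an estimated correlation and 0.0973 without control replicates 1 and 2, and their median was 0.34 without DEHP replicate 3. Hepatocyte markers did not pass (median -0.06, mean 0.04, adjusted p = 0.718), nor did cholangiocyte markers (-0.33, adjusted p = 0.842), although Krt23 belongs to that list. The cholangiocyte median was -0.08 without control replicate 2 and 0.01 without control replicate 3, and the list passed the mixed fry test (adjusted p = 3.39e-04). The hepatocyte median was 0.12 without control replicate 3.

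Genes higher in female than in male mouse liver had a median of 0.99 over 13 tested (camera adjusted p = 9.78e-05), with adjusted p = 0.409 with an estimated correlation. That list holds Cd36, the member past the threshold over all genes in the filtered edgeR fit of all libraries. Of the list, 3 of 18 passed with no filter and 2 of 14 without control replicate 3. Xist, a transcript of female cells, had 5, 5 and 0 counts in control replicates 1 to 3 and 2, 3 and 0 in the exposed replicates. These counts give no sign of a sex difference between the groups, though no row on chromosome Y can check it. The male-biased list did not pass (median -0.05, mean 0.05, adjusted p = 0.371), with a median of 0.14 without control replicate 3 and -0.31 without DEHP replicate 2, and adjusted p = 5.54e-05 in the mixed fry test. Pericentral hepatocyte genes had a median of 0.48 (15 of 22 positive, camera adjusted p = 4.65e-04), with adjusted p = 0.409 with an estimated correlation and 0.0557 without control replicates 1 and 2, with 4 higher and 1 lower past the threshold over all genes without control replicate 3. Periportal genes had a median of 0.16 (camera adjusted p = 0.148, and 0.00560 without control replicate 3 or 0.0362 without DEHP replicate 1), with adjusted p = 0.724 with an estimated correlation. The periportal median ran from 0.04 without control replicate 1 to 0.32 without control replicate 3. The list of acyl-CoA thioesterase genes had all 10 positive (median 0.79, camera adjusted p = 9.78e-05), with adjusted p = 0.409 with an estimated correlation. Its median was 0.46 without control replicate 1 and 0.47 without DEHP replicate 3. Endoplasmic reticulum stress genes had a median of -0.31 (camera adjusted p = 0.00640), with adjusted p = 0.479 with an estimated correlation, 0.181 without control replicate 3 and 0.138 without DEHP replicate 3 (median -0.20). Immediate-early and heat shock genes, which rise with handling and tissue stress, were lower as a list too (median -0.43, camera adjusted p = 0.00640), with adjusted p = 0.409 with an estimated correlation and 0.0570 without control replicate 1. Calr and Hspa5, chaperones of the endoplasmic reticulum, had -0.41 ± 0.22 and -0.48 ± 0.25.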
